A study of Drosophila melanogaster with 16 samples.

How the data were processed

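Chromatin bound by tagged Polycomb group proteins was measured by BioTAP-XL ChIP-seq, in which a protein carrying an affinity tag is crosslinked to chromatin, purified in tandem, and its DNA sequenced. The baits were Scm (Sex comb on midleg), Pc (Polycomb, a subunit of PRC1) and E(z) (Enhancer of zeste, the histone methyltransferase of PRC2). The sources were Drosophila melanogaster embryos collected 12 to 24 h after fertilization and S2 cells, a male embryo-derived cell line. Per the labels, 16 libraries (IP and matched input) were made, and they fall into 5 combinations of bait and source. Scm in embryos and Pc in S2 cells have 1 IP and 1 input library each. Pc in embryos, E(z) in embryos and Scm in S2 cells have 2 of each. E(z) in S2 cells was not analysed here.

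The authors deposited 1 enrichment profile per combination, so the replicates of a group are pooled and no spread between replicates can be given. The deposited values are log2 enrichment of IP over input, with 1 value every 20 bp, or every 50 bp for Pc in S2 cells. The file headers do not state the scale. It was read from the deposited values, which lie partly below 0 and show isolated bumps of repeated heights above the single value found where no reads lie. The commonest height was between 0.95 and 1 in 4 profiles and between 1.55 and 1.6, around the log2 of 3, in the Scm S2 profile. Reads were aligned with Bowtie 0.12.7, per the submitters' processing notes. The tool that made the profiles, its smoothing width and the genome build are not given in the sources used here. Sequencing depth is unknown, so no counting interval was computed. Smoothing widens narrow peaks, and enrichment at thinly covered positions is noisy because few reads decide it.

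Positions are those of the deposited profiles, written 1-based. The sequence names (2L to X, the Het sequences, U and Uextra) and their extents are those of Release 5 of the genome. The gene table at hand is of Release 6, in which the arms have other lengths, so no coordinate was converted and no gene was placed on a region. The 11 gene lists fixed before the data were examined, Hox and segmentation genes among them, were for this reason not tested, and regions are named by position.

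Values were averaged in 500-bp bins, and bins without reads were left out. The median over a profile's bins with reads was subtracted. The design had foreseen linear values divided by the median, and on the log2 scale a threshold of 4 times the median bin became a difference of 2. Bins at or above it were joined over gaps of up to 1 kb, and regions under 1 kb were dropped. The mitochondrial sequence was left out of the comparisons. The shares of regions touched by another profile's regions (at least 1 bp) have exact binomial 95% intervals. Their chance level came from 1000 circular shifts of the other set within each chromosome sequence (one-sided), with Benjamini-Hochberg adjustment over the 12 shares. The smallest p these shifts can give is 0.000999. Spearman's rho across bins, signal around summits, sequence ratios and median differences have 95% intervals from a bootstrap of 1-Mb blocks, with 1000 draws (300 for summits, 500 for differences). Chromosome 4 ends at position 1323739 and so fills 1 block and part of another. Its intervals rest on few distinct draws and are rough. All these intervals and p-values describe variation along the genome within these profiles. They do not cover the variation between embryo collections or cultures, and bins and regions are not replicates.

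The rule for named regions, fixed before the data were examined, takes the 10 regions with the highest mean in each comparison's first profile and the 10 with the highest and the 10 with the lowest log2 ratio over the union of regions. Widest regions, and the highest regions of profiles that are not the first of a comparison, lie outside that rule and were chosen after their values were seen. The alternatives fixed before the data were examined were thresholds of 3 and 6 times the median and the top 1% of bins, bins of 200 bp, 1 kb and 5 kb, no joining or joining over 3 kb, values without scaling, main arms only, an overlap of 50% of the region, bins enriched in either profile, summits of Pc regions, scaling to shared regions and a pseudocount of 1. Added later were shares without X, 1 median per sequence, the sign-flipped profile, the 100 highest regions, the arm ends without that of 3L, and the difference on X with 1 median per sequence or over the main arms.

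The procedure was tested on simulated profiles over 337345 bins with the noise spread and autocorrelation of each profile and planted regions. Of planted regions 3.5 above the median on the log2 scale, 97.9% were recovered with the noise of the Scm embryo profile and 95.8% with that of the Scm S2 profile. Noise alone gave 2 regions with the spread of the Scm embryo profile, 286 with that of the Pc embryo profile, 5 with that of E(z), 975 with that of the Scm S2 profile and 1001 with that of the Pc S2 profile. The simulated numbers for both S2 profiles exceed the regions called in the real profiles, so the simulated noise is wider than the noise that made those calls. The spread was taken from all bins above the median, true signal included, so the simulated noise may be too wide in every profile. Single low regions of the S2 profiles and of the Pc embryo profile still cannot be told from noise by height. The computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.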

Results

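The data consist of 5 genome-wide log2 enrichment profiles, for Scm, Pc and E(z) in embryos of 12 to 24 h and for Scm and Pc in S2 cells. Each is pooled from 1 or 2 pairs of IP and input libraries, so none of the differences below has a replicate check. All values are relative to the median bin of the same profile. Reads covered 96.3%, 96.2% and 96.2% of the 500-bp bins on the main arms in the Scm, Pc and E(z) embryo profiles, 97.46% in Scm S2 and 97.2% in Pc S2. Over all sequences they covered 79.1%, 78.7% and 79.0% in embryos, but 91.0% in Scm S2 and 88.4% in Pc S2. The spread of bins around the median (SD from the median absolute deviation) was 0.49, 0.75 and 0.55 on the log2 scale for Scm, Pc and E(z) in embryos, and 1.10 and 1.05 for Scm and Pc in S2 cells.

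Enriched regions differed in number and in breadth between the baits. In embryos, Pc had 796 regions covering 3196 kb (95% interval 2431 to 4022 kb), E(z) 472 regions covering 2582 kb (1928 to 3299 kb) and Scm 392 regions covering 1098 kb (784 to 1470 kb). Wide regions of at least 10 kb numbered 66 for Pc and 72 for E(z) but 8 for Scm. At shared regions the median log2 difference was -0.71 for Scm minus Pc and -0.47 for Scm minus E(z). A fixed threshold cuts a lower signal into shorter regions, so the numbers of wide regions do not measure breadth alone. In S2 cells, Scm had 534 regions covering 1043 kb (834 to 1256 kb) and Pc 382 regions covering 999 kb (763 to 1272 kb), of which 1 and 8 were at least 10 kb wide. Regions of the Scm S2 profile were the shortest, with a median width of 1.5 kb, against 2 kb for Scm and Pc in embryos and 2.75 kb for E(z). These counts moved by more than 1.5 times with the threshold. Under the same rule the sign-flipped profile gave 15, 113 and 3 regions for Scm, Pc and E(z) in embryos but 4268 for Scm and 2824 for Pc in S2 cells, so strong depletion was common in both S2 profiles.

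Polycomb group proteins keep developmental genes, the Hox genes among them, silenced. The first comparison asked whether Scm sits at the sites of PRC1 and PRC2, the pair of complexes to which Pc and E(z) belong. In embryos it did so at most of its regions. Of the 392 Scm regions, 354 (90.3%, 86.9 to 93.0%) touched a Pc region and 344 (87.8%, 84.1 to 90.8%) touched an E(z) region. Circular shifts gave 4.05% and 2.93% on average and 23.5% and 23.7% at the most (adjusted permutation p = 0.000999 for each, the smallest the shifts can give). In the other direction the shares were lower, at 37.6% of Pc regions (34.2 to 41.0%) and 56.8% of E(z) regions (52.2 to 61.3%) with a Scm region. Among the 100 highest regions on the main arms, a set chosen after the data were seen, they were 83% of Pc regions (74.2 to 89.8%) and 85% of E(z) regions (76.5 to 91.4%), so the lower shares come largely from weaker regions. Pc and E(z) shared 51.1% of Pc regions and 80.7% of E(z) regions. Among the 840 regions of the union, 244 held all 3 baits, 362 Pc alone, 110 Pc and E(z), 72 E(z) alone, 20 Scm and Pc, 11 Scm and E(z), and 21 Scm alone. Where no Pc or E(z) region was called at a Scm region, the median values were 0.70 for Pc (38 regions) and 1.67 for E(z) (48 regions). The Pc value lies within the spread of 0.75 of that profile's single bins. No interval of this median over regions was computed, so it neither shows nor excludes Pc there. At Pc regions without a call the median values were 1.085 for Scm (497 regions) and 1.09 for E(z) (389 regions), so a missing Scm or E(z) call need not mean a missing bait. Simulated noise with the spread of the Pc embryo profile gave 286 regions, with mean log2 values up to 3.24, so some regions of Pc alone cannot be told from noise by height. The simulated spread came from bins above the median, true signal included. The sign-flipped Pc profile gave 113 regions, 22 of them on the main arms. The 286 is therefore no estimate of how many Pc regions are noise.

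**Figure D1:**
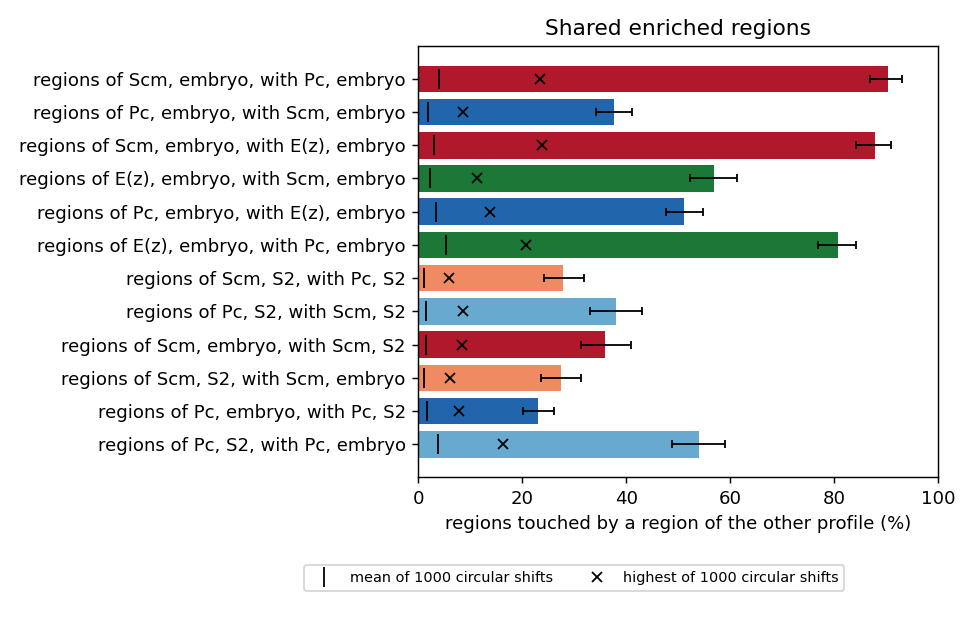
Percent of the regions of one profile (bars, with exact binomial 95% intervals) that are touched by a region of another, with the mean (vertical marks) and the highest value (crosses) of 1000 circular shifts. The bars of Scm in embryos reach 90.3% with Pc and 87.8% with E(z), and that of Scm with Pc in S2 cells 27.9%.

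Several of the highest Scm regions of embryos carried all 3 baits. At 3L 9033501 to 9035000 the mean log2 values were 3.84 for Scm, 5.48 for Pc and 3.69 for E(z). At X 2017001 to 2021000 they were 3.63, 5.36 and 2.68, at 3L 6896001 to 6898000 they were 3.53, 4.22 and 3.16, and at 2R 5081501 to 5083500 they were 3.45, 4.51 and 3.33. Of the other 6 among the highest 10, 5 lay on the unplaced sequences U and Uextra, and the last, X 10001 to 12500 near the end of the arm, had 3.49 for Scm, 0.96 for Pc and 1.61 for E(z). Over the union of Scm and Pc regions the Scm value was lower than the Pc value by a median log2 difference of -1.05 (-1.15 to -0.97, 830 regions). Against E(z) it was -0.53 (-0.61 to -0.48, 517 regions). Scaled to the regions both profiles share, these differences were -0.34 (-0.44 to -0.26) and -0.065 (-0.14 to -0.013), so most of their size depends on the scaling. The scaling value was held fixed in these intervals, so its own uncertainty is left out. The scaled interval against E(z) therefore does not show that 0 is excluded. The 10 regions with the highest ratio of Scm to Pc all lay on U or Uextra. The 10 with the lowest lay on the main arms, among them 3R 8326501 to 8328000, where Pc reached 4.21 with Scm at 0.89 and E(z) at 0.22, and 4 90501 to 97000, where Pc was at 2.90 with Scm at -0.21 and E(z) at -0.10. The lowest ratios of Scm to E(z) included 4 of 10 regions within 3L 17962001 to 18017500, with E(z) between 2.14 and 2.34 and Scm between -0.80 and -0.34. E(z) also stood alone in embryos at 4 1284001 to 1285500, with 3.45 against 0.69 for Scm and -0.19 for Pc. This site lies in the last 50 kb of chromosome 4, where 35% of bins had reads in the E(z) profile. Few reads may decide its values.

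Around the summits of Scm regions the E(z) signal fell off more slowly, relative to its height at the summit, than Scm and Pc. At 372 summits on the main arms the median log2 value was 3.05 for Scm (3.00 to 3.12), 3.66 for Pc (3.52 to 3.84) and 2.94 for E(z) (2.78 to 3.04). Widths were read at 50% of the log2 value at the summit, with the profile's median bin at 0. For these embryo profiles 50% of the enrichment itself lies at a higher level, where the widths would be narrower. The width at 50% of the log2 value was 3.65 kb for Scm (2.98 to 4.58), 5.59 kb for Pc (4.38 to 6.87) and 18.5 kb for E(z) (12.5 to 30.4). At 5 kb from the summit E(z) was still at 1.67 and Pc at 1.56, with Scm at 1.23. At 10 kb E(z) was at 1.45 and Pc at 1.37. The lower summit value of E(z) also lowers the level at which its width is read. Scm in S2 cells, whose regions were the shortest, had a width of 24.7 kb at these summits (10.6 to 34.5). Widths at summits of E(z) regions were not computed. Summits of shared regions lay within 0.5 kb of each other at 70.1% of regions shared by Scm and Pc and at 64.2% of those shared by Scm and E(z). For Scm in embryos and S2 cells it was 72.3%. In 500-bp bins this distance means the same or an adjacent bin. Shared regions already touch, and no chance level was computed. Choosing Scm summits favours a narrow Scm peak, and at Pc summits the order of Scm and Pc turned, with widths of 8.32 kb for Scm (4.86 to 14.1), 5.32 kb for Pc (4.42 to 6.92) and 25.6 kb for E(z) (18.0 to 36.1).

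**Figure D2:**
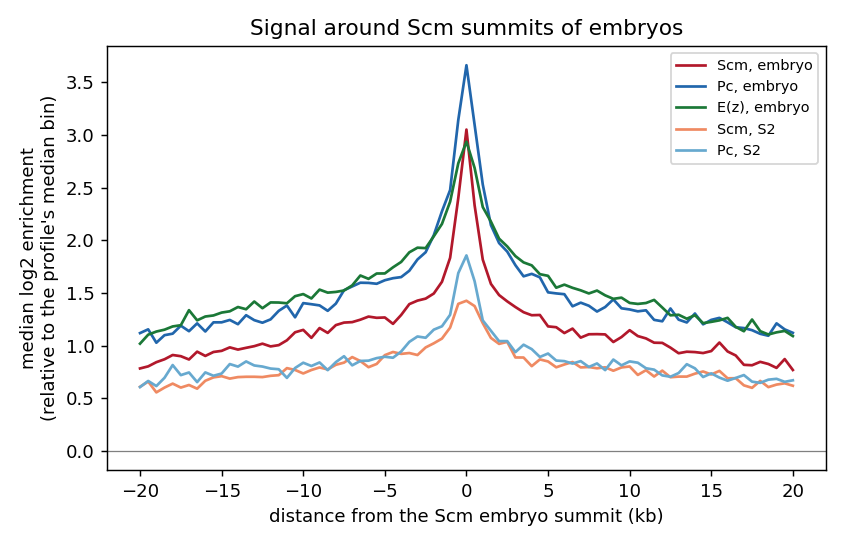
Median log2 enrichment (vertical axis, relative to each profile's median bin) against distance from 372 Scm summits of embryos in kb, 1 line per profile. The Scm line falls to 1.83 at 1 kb from a summit of 3.05, and the E(z) line from 2.94 to 2.34.

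The widest region was a domain on 2R that filled 94 kb in the E(z) profile (8836501 to 8930500, mean 3.35) and 92.5 kb in the Pc profile (8838501 to 8931000, mean 3.88). Over the 94 kb, Scm in embryos was enriched in 6 separate regions covering 56 kb, or 59.6%, with a mean of 2.02. That mean lies at the threshold of 2, so the breaks depend on where the cut is made. The Scm bins between these regions all lay above the profile's median bin, the lowest at 0.34. The breaks therefore do not show that Scm is absent there. In S2 cells Pc covered 84 kb of it in 4 regions, while Scm covered 19.5 kb in 5 regions, or 20.7%. A second dense stretch, on 3R, held the widest Scm region of embryos (12756501 to 12781500, 25 kb). In the 400 kb from 12.45 to 12.85 Mb around it, enriched regions covered 126 kb for Scm, 230 kb for Pc and 182.5 kb for E(z) in embryos, and 37.5 kb for Scm and 22 kb for Pc in S2 cells. Both stretches were chosen after the values were seen.

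**Figure D3:**
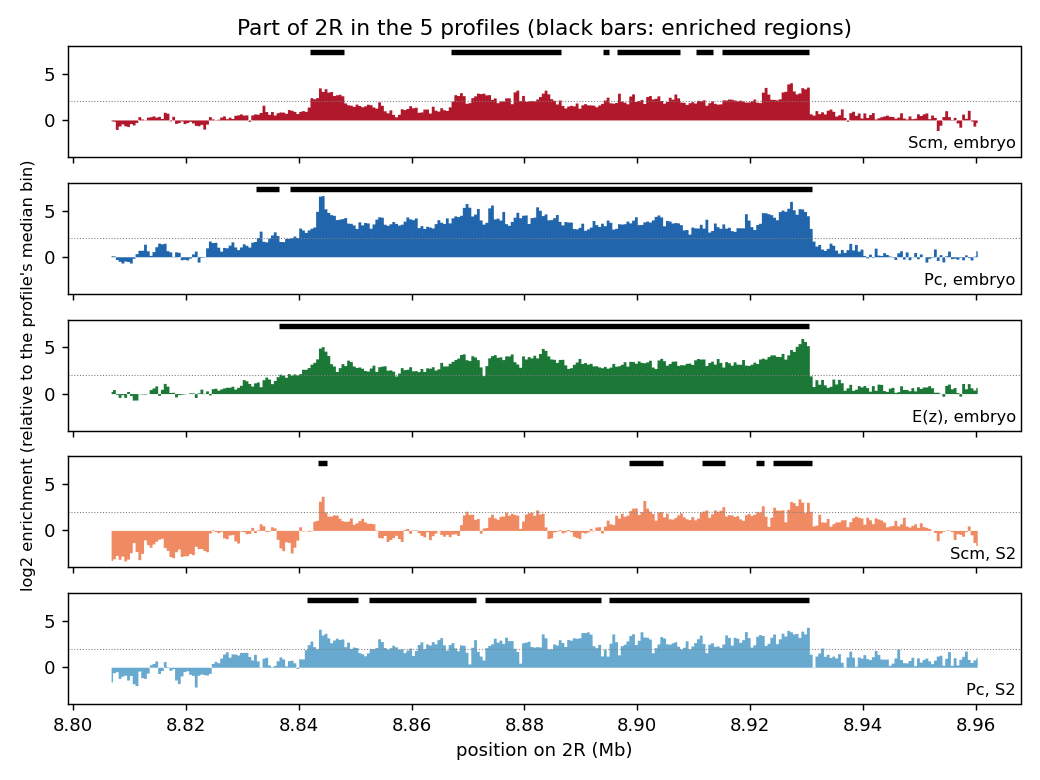
Log2 enrichment in 500-bp bins (vertical axes, relative to the profile's median bin) along 2R in Mb, 1 panel per profile, with enriched regions as black bars and the threshold of 2 dotted. In embryos Pc and E(z) have 1 region each over the domain, and Scm has 6 that cover 59.6% of it.

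**Figure D4:**
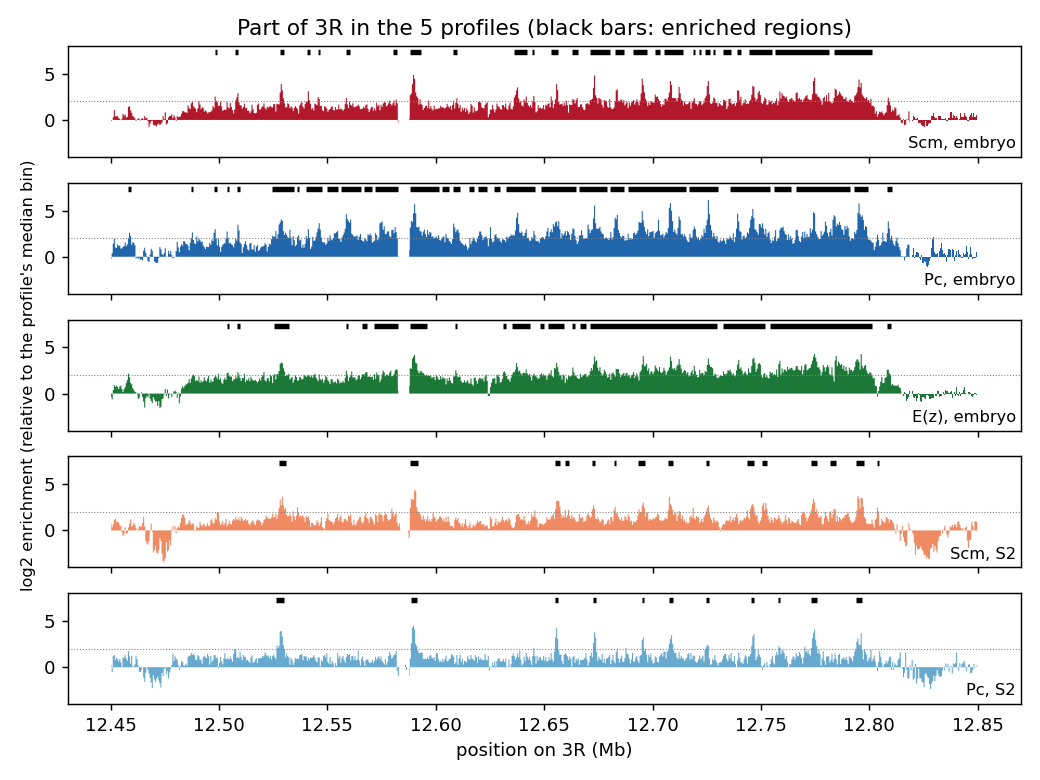
The same for 3R from 12.45 to 12.85 Mb. Bins without reads are blank, and 27 Scm regions and 29 Pc regions of embryos lie here, against 15 and 11 in S2 cells.

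In S2 cells fewer of the Scm regions had a Pc region. Of 534 Scm regions, 149 (27.9%, 24.1 to 31.9%) touched a Pc region, and of 382 Pc regions, 145 (38.0%, 33.1 to 43.0%) touched a Scm region. Shifts gave 1.03% and 1.46% on average (adjusted permutation p = 0.000999 for each). The share of Scm regions with Pc was lower than in embryos by 62.4 percentage points (56.5 to 68.1, bootstrap of blocks), and the share of Pc regions with Scm differed by -0.40 points (embryo minus S2), with an interval from -6.78 to 6.495. Pc had 796 regions in embryos against 382 in S2 cells, and a smaller Pc set can touch fewer Scm regions. Of the 100 highest Pc regions on the main arms 85% had a Scm region in S2 cells (76.5 to 91.4%), against 83% in embryos. Pc regions of S2 cells that were high in all 5 profiles included 2R 3906001 to 3907000, with 4.24 for Pc and 3.05 for Scm in S2 cells and 4.41, 4.59 and 4.52 for Scm, Pc and E(z) in embryos. At 3R 4006501 to 4008500 Pc was at 3.68 and Scm at 2.78 in S2 cells, and at X 5487501 to 5489500 they were at 3.59 and 2.87. Scm regions high in S2 cells without a Pc region included 4 423001 to 434500, 11.5 kb wide, with 3.97 for Scm and -0.22 for Pc, and 2R 6149001 to 6150500, with 4.29 and -0.95. The median Pc bin of chromosome 4 lay at -1.58 in S2 cells, so Pc at the first of these was above its level on that chromosome. Of the 10 highest Scm regions of S2 cells the other 8 lay on U and Uextra. Noise in the S2 profiles was wide, single low regions cannot be told from it, and the share with Pc rose from 15.1% at 3 times the median to 44.6% at 6 times.

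Between embryos and S2 cells, each bait kept part of its regions. Scm regions of embryos had a Scm region in S2 cells at 141 of 392 (36.0%, 31.2 to 40.9%), and Pc regions of embryos had a Pc region in S2 cells at 183 of 796 (23.0%, 20.1 to 26.1%). Of the S2 regions, 27.3% of Scm (23.6 to 31.3%) and 53.9% of Pc (48.8 to 59.0%) had one in embryos. All 4 shares exceeded every shift (adjusted permutation p = 0.000999). Embryo regions of Scm that were low in S2 cells included X 2575501 to 2576500, with 2.53 in embryos and -2.54 in S2 cells, 3R 26606501 to 26609000, with 2.92 and -1.36, and 4 724501 to 726000, with 3.05 and -0.71. For Pc, 5 of the 10 highest ratios of embryos to S2 cells lay on chromosome 4, among them 4 102501 to 112000, with 3.11 in embryos and -2.42 in S2 cells. The median Pc bin of the whole chromosome lay at 0.47 in embryos and -1.58 in S2 cells, which enters these ratios. Pc regions higher in S2 cells included X 825001 to 826500, with -0.66 in embryos and 2.80 in S2 cells, and 2L 6396001 to 6397000, with -0.95 and 2.49. Simulated noise of the Pc S2 spread, although wider than the real noise, reached 3.47. Neither region can be told from noise by height. The median difference over the union was 1.44 for Pc (1.33 to 1.55, 952 regions, embryo minus S2) and -0.13 for Scm (-1.21 to 0.35, 724 regions). Scaled to the shared regions these differences were 0.62 (0.51 to 0.73) and -0.51 (-1.58 to -0.030). The scaling value was held fixed in these intervals, so the upper bound for Scm does not show that 0 is excluded.

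Across all bins, Spearman's rho was 0.29 between Scm and Pc in embryos (0.27 to 0.32), 0.37 between Scm and E(z) (0.34 to 0.39) and 0.42 between Pc and E(z) (0.40 to 0.45). It was 0.41 between Scm and Pc in S2 cells (0.38 to 0.43), 0.43 between Scm in embryos and S2 cells (0.41 to 0.45) and 0.22 between Pc in embryos and S2 cells (0.17 to 0.26). These 6 values are across bins, which are not independent. Within bins enriched in either profile the sign turned for Scm and Pc in S2 cells (-0.23) and for Scm in embryos and S2 cells (-0.27).

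The chromosome comparison was made because S2 cells are male-derived, while the labels give no sex for the embryos. Scm regions of S2 cells were concentrated on X, where 154 of them lay, and the share of enriched bins was 2.20 times the share of bins with reads (1.59 to 2.77). In embryos this ratio was 1.19 for Scm (0.61 to 1.88), 0.92 for Pc (0.55 to 1.35) and 1.18 for E(z) (0.63 to 1.77), and for Pc in S2 cells it was 1.39 (0.85 to 2.01). With 1 median per sequence the Scm S2 ratio on X was 1.27 (0.84 to 1.70). On chromosome 4, which is small and rich in heterochromatin, Pc of embryos had 29 regions and a ratio of 5.47 (4.30 to 7.13), E(z) 1.62 (1.19 to 2.62) and Scm 1.26 (0.86 to 2.37). Scm in S2 cells had 6.19 there (2.30 to 19.3) with 17 regions, and Pc in S2 cells 0.18 (0.00 to 0.85) with 1 region. With 1 median per sequence the Pc S2 ratio on 4 turned to 6.38 (1.90 to 22.6), since the median bin of the chromosome lay at -1.58 in that profile. Chromosome 4 fills 1 block of 1 Mb and part of another, so all its intervals rest on few distinct draws and are rough. With 1 median per profile the Het sequences had few enriched bins, with ratios of 0.060, 0.069 and 0.039 for Scm, Pc and E(z) in embryos and 0.22 and 0.021 for Scm and Pc in S2 cells. With 1 median per sequence the S2 ratios were 1.03 for Scm (0.64 to 1.46) and 1.08 for Pc (0.69 to 1.61), while those of embryos stayed between 0.073 and 0.20.

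**Figure D5:**
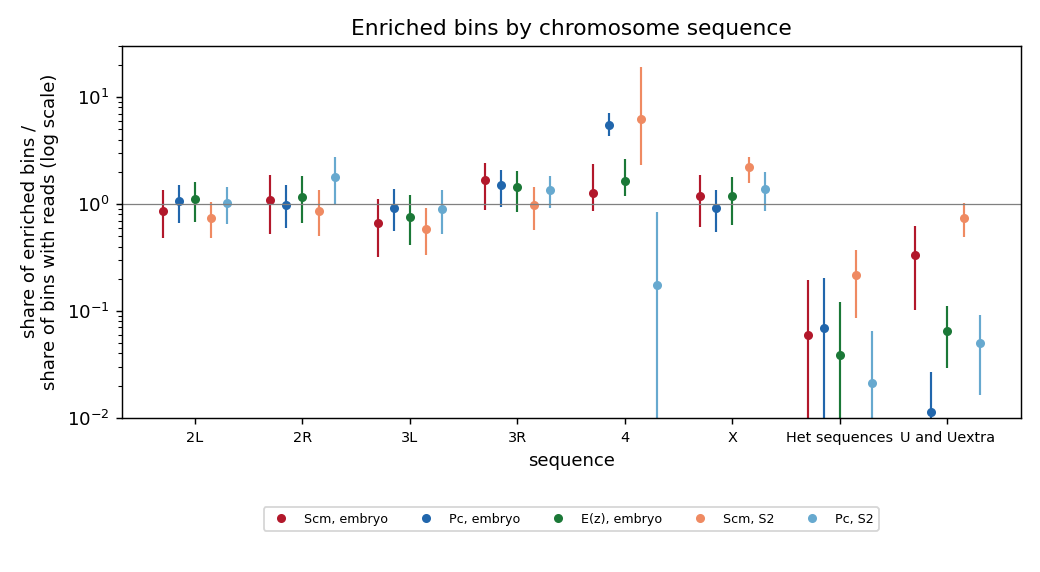
Share of enriched bins divided by the share of bins with reads (log axis) per chromosome sequence, 1 point per profile with block bootstrap 95% intervals; intervals reaching 0 run to the lower edge of the plot. Pc of embryos stands at 5.47 on chromosome 4 and Scm of S2 cells at 2.20 on X.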

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

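The tests of a shift of the whole of chromosome 4 in either source, of heterochromatin-like sequence, of X sites recovered whatever the bait and of X sites particular to S2 cells were chosen after the results were seen, as were the X ratios over the main arms, the difference on X with 1 median per sequence and the condition that leaves noise on X undecided. The rules of the other tests in this part were written before their results were seen, although shares without X and among the 100 highest regions, 1 median per sequence and the sign-flipped profile were settings added after the data were seen. None of them has replicates.

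The share of Scm regions with a Pc region differed between sources, with 90.3% in embryos and 27.9% in S2 cells (difference 62.4 percentage points, 56.5 to 68.1). The Pc sets were unlike in size, with 796 regions covering 3196 kb in embryos and 382 covering 999 kb in S2 cells. A smaller Pc set can touch fewer Scm regions, also among the 100 highest. How much of the difference set size makes was not tested. Over the main arms without X the share was 44.4% in S2 cells (38.3 to 50.7%) against 96.6% in embryos. This set also leaves out the Het and unplaced sequences. At S2 regions of Scm without Pc the median Pc value was -0.26 (-0.42 to -0.07), well under the threshold, which noise calls of Scm would give too. These values argue against the extra Scm regions on X, and against Pc just under the threshold, as the whole of the difference. Among the 100 highest Scm regions on the main arms the share was 52% in S2 cells (41.8 to 62.1%) and 97% in embryos (91.5 to 99.4%). This does not decide on weak regions near the noise. Simulated noise of the Scm S2 spread, although wider than the real noise, reached 3.42, and Scm S2 regions had a median of 2.42. The other direction shows no such gap, with a Scm region at 85% of the 100 highest Pc regions in S2 cells and 83% in embryos, and noise may still account for part of the gap of Scm, since the S2 share rose from 15.1% at 3 times the median to 44.6% at 6 times. A difference between the sources, and one between tagged lines and culture batches, stays open and untested. Unlike processing or mapping of the profiles was not tested either. On Uextra 14.1% of the points of the Scm embryo profile had reads, against 66.6% in the Scm S2 profile. Off the main arms lay 119 of the 534 Scm regions of S2 cells and 20 of the 392 of embryos.

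Scm on X also differed between sources, with ratios of 2.20 in S2 cells and 1.19 in embryos (log2 difference 0.89, 0.35 to 1.61). Sites recovered whatever the bait are argued against as the main source by a median Pc S2 value of 0.19 (-0.13 to 0.56) over all 154 X-linked Scm regions, of which 18.2% had a Pc region, against 44.4% of the 261 on the autosomes. X sites particular to S2 cells remain a candidate, since 19.5% of the X-linked regions had a Scm region in embryos against 42.9% on the autosomes (one-sided Fisher's exact p = 5.8e-07), which regions added by a shift or by noise would give too. Noise on X is not decided, because an upward shift of X would itself lower the ratio of the sign-flipped profile, 1.07 (0.90 to 1.26). A shift of the whole X also stays open: the S2 ratio was 1.27 (0.84 to 1.70) with 1 median per sequence, 1.97 (1.46 to 2.49) over the main arms and 1.42 (0.96 to 1.93) with both, and with 1 median per sequence the log2 difference between sources was 0.41 (-0.19 to 1.10) over all sequences but 0.70 (0.20 to 1.38) over the main arms.

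Pc on chromosome 4 differed the other way, with a ratio of 5.47 in embryos and 0.18 in S2 cells (log2 difference -4.96, -8.22 to -2.75). Chromosome 4 fills 1 block of 1 Mb and part of another, so the intervals here rest on few distinct draws and are rough. The S2 ratio rests on 1 region and its interval reaches 0.00, so -8.22 cannot be taken as a bound. For the embryo concentration, a shift of the whole chromosome is argued against as its only cause by a ratio of 3.37 (2.60 to 4.84) with 1 median per sequence, and heterochromatin-like sequence in general by a ratio of 0.069 (0.00 to 0.20) over the Het sequences. Whether these sites carry E(z) as often as elsewhere stays open, with 37.9% of 29 regions against 51.6% of 762 on the other arms (one-sided Fisher's exact p = 0.105), too few to decide. For the difference between sources, a lower Pc signal over the whole of chromosome 4 in S2 cells is a candidate explanation: with 1 median per sequence the S2 ratio was 6.38 (1.90 to 22.6). The cause of that lower signal was not tested.

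The ratio of Pc on X was also higher in S2 cells than in embryos, at 1.39 and 0.92 (log2 difference 0.60, 0.15 to 1.06). The ratio of Scm on chromosome 4 was 6.19 in S2 cells and 1.26 in embryos (log2 difference 2.30, 1.01 to 3.34, an interval that rests on few distinct draws of blocks). In the mitochondrial sequence, which the comparisons leave out, 1 bin of 21 with reads in the Pc embryo profile passed the threshold, at 2.97, while the highest bins of the other 4 profiles lay between -0.48 and 0.97.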

How the results depend on the processing

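The sign-flipped profile, 1 median per sequence, the shares without X, the 100 highest regions, the ends without 3L and the recomputed difference on X were chosen after seeing the data. No paired analysis was possible because each group has 1 pooled profile, and for the same reason no replicate could be left out. All 78 alternative shares of shared regions stayed above chance with p under the threshold of 0.05, although their size moved: with the top 1% of bins the share of Scm embryo regions was 68.8% with Pc and 67.7% with E(z), and among the 100 highest regions the share with Scm rose to 83% for Pc and 85% for E(z) in embryos and to 85% for Pc in S2 cells. The log2 ratios of named regions were also recomputed, but a pseudocount cannot turn their sign and the scaling moves them by less than their size, so this tests nothing. The cause of the changes below was not tested unless stated. Depth is unknown, so what it limits cannot be quantified.

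Region counts at 3 and 6 times the median were 613 and 233 for Scm, 1339 and 469 for Pc and 716 and 267 for E(z) in embryos, and 1549 and 195 for Scm and 1247 and 180 for Pc in S2 cells. The covered lengths were 2316 and 411.5 kb, 5816 and 1508 kb, 4773.5 and 975 kb, 3251 and 340.5 kb, and 3146.5 and 376 kb in the same order, a change that the threshold makes by construction. Without scaling, Pc of embryos covered 1836.5 kb and E(z) 1682 kb. The sign-flipped profiles gave 15, 113, 3, 4268 and 2824 regions in the same order.

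Within bins enriched in either profile, Spearman's rho reversed to -0.23 for Scm and Pc in S2 cells and to -0.27 for Scm in embryos and S2 cells, and was 0.083 (-0.022 to 0.19) for Pc in embryos and S2 cells. Choosing bins that are high in either profile lowers the correlation by construction. At Pc summits the median values were 1.74 for Scm, 2.92 for Pc and 1.93 for E(z) in embryos and 1.06 and 0.91 for Scm and Pc in S2 cells, and the Scm embryo width was 8.32 kb against 5.32 kb for Pc. The width of Pc in S2 cells gave no value there, since the curve did not fall to 50% of its log2 value at the summit within 20 kb.

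At 3 times the median the sequence ratio was 1.57 for Scm of embryos on 4, 0.92 for Scm of S2 cells on 3L and 0.45 on U and Uextra, and 1.59 for Pc of S2 cells on both 2R and X. At 6 times it was 1.47 for E(z) on 4 and 0.57 for Scm of S2 cells on 2L. With the top 1% of bins it was 1.40 for Scm of embryos on 4, 0.73 for Scm of S2 cells on U and Uextra, and 1.76 on 2R and 0.24 on 4 for Pc of S2 cells. With 1 median per sequence it was 0.43 on 2L, 1.27 on X, 1.03 on the Het sequences and 1.43 on U and Uextra for Scm of S2 cells, and 6.38 on 4 and 1.08 on the Het sequences for Pc of S2 cells. A low median of a sequence raises the calls there and a high one lowers them. Scaled to the shared regions, the median log2 difference over regions kept its sign but shrank to -0.34 for Scm minus Pc and -0.065 for Scm minus E(z) in embryos and to 0.62 for Pc in embryos minus S2 cells. It was 1.13 (0.38 to 2.09) for Scm minus Pc in S2 cells and -0.51 (-1.58 to -0.03) for Scm in embryos minus S2 cells, where the intervals of the main values include 0. The scaled intervals leave out the uncertainty of the scaling value, so they do not show that 0 is excluded.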

Other observations

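The tests of the telomeric arm ends, with and without that of 3L, and of Pc sites of embryos were chosen after the results were seen, and the test of kept regions before.

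Embryo regions of all 3 baits fell into 2 groups in S2 cells. Of the 244, 109 had both a Scm and a Pc region in S2 cells, 99 neither, 31 Pc alone and 5 Scm alone. The odds ratio was 69.6 (24.0 to 226, bootstrap of blocks; Fisher's exact p = 1.26e-33, two-sided), so Scm and Pc were found at largely the same embryo regions. The regions with both had a median width of 12 kb in embryos and those with neither 4.5 kb, and a wider region has more room to be touched. Their median Scm values in embryos were close, at 1.90 and 1.79, and so were the Pc values, at 2.60 and 2.51. One hypothesis is that Scm and Pc are held or lost together at a site, to which this odds ratio is open but which width and local depth could also produce.

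Some telomeric ends of the chromosome arms were rich in enriched bins, and unevenly so. In the last 50 kb of the 6 ends together, 16.3% of bins were enriched for Pc in embryos, against 2.75% over the main arms (circular-shift permutation p = 0.023), but 58 of its 85 enriched bins lay on 2R and none on X or 4. E(z) had 15.5% (permutation p = 0.00999), with 55 of 81 bins on 2R, and Scm 11.6% (permutation p = 0.002), with 34 of 60 bins on 3L. The ends were unevenly covered: on 3L only 39 of 100 bins had reads in either S2 profile, and on 4 between 31 and 36 in embryos against 86 to 90 in S2 cells. At the 5 ends without 3L the shares were 6.22% for Scm, 19.0% for Pc and 17.5% for E(z) in embryos and 21.8% for Scm and 5.45% for Pc in S2 cells (permutation p = 0.026, 0.018, 0.012, 0.000999 and 0.017). Of the 101 end bins of Scm in S2 cells, 35 lay on 4 and 27 on X. At 2L 5001 to 9000 all 5 profiles were high, with log2 values of 2.87, 3.76 and 3.31 for Scm, Pc and E(z) in embryos and 2.75 and 3.02 for Scm and Pc in S2 cells. Reads shared between repeats near telomeres were not tested.

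Scm regions of S2 cells without Pc in S2 cells did coincide with Pc of embryos in part. Of 271 such regions on the main arms, 51 (18.8%) touched a Pc region of embryos, against 10.2 on average and 23 at the most in the shifts (permutation p = 0.000999). With Scm of embryos the count was 12 and with E(z) 18, against 3.46 and 7.15 on average in the shifts (permutation p = 0.004 and 0.005). The highest shifts, 13 and 20, exceeded both counts. Their median values in embryos were 1.02 for Pc, 0.39 for Scm and -0.25 for E(z). These sites may therefore include Pc sites of embryos that lack Pc in the S2 profile, although most of them touched no Pc region of embryos.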
